A study of Rattus norvegicus with 24 samples.

How the data were processed

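Liver RNA of 24 rats was measured by sequencing of polyA-selected RNA on an Illumina NextSeq instrument. The 24 libraries form 4 groups of 6: males and females, each from dams that had breathed filtered air or ozone. The labels carry the sex of each animal under a tag named for genotype. They give no dam or litter for an animal, so littermates may be among the 24. The p-values rest on the spread between these animals, taken as independent. Littermates within a group could make them too small.

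Total RNA with RIN values above 7 was used, per the labels' protocols. The submitters' processing notes name Partek (no version), STAR 2.6.1d, the genome build rn6 and DESeq2, with no role or order. The gene annotation and its release, trimming, strand setting and filters are not given in the sources used here. The authors deposited estimated counts per gene, 1 table per sex, each with 18056 Ensembl rat gene IDs. These expected counts are not divided by library size or gene length, per the file headers and the values, and between 74.4% and 81.3% of a library's values are whole within 1e-09. Fractional values arise where reads are divided between genes. Strand use is not known, so overlapping and antisense genes cannot be told apart. The tables hold 23 further library columns, 12 in the female table and 11 in the male table, which match none of the 24 samples and were not used here. The response to ozone after birth itself is therefore not analysed here.

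The files do not pair the gene IDs with names, and 0 of the 18056 IDs matched the reference table used here. No gene is named, and the 41 gene lists fixed before the data were examined (pathways and cell type markers) were not tested. The rule fixed for naming genes passed over IDs without a symbol. In its place, the 2 largest rises and 2 largest falls per sex are given by ID, among genes with adjusted p under 0.05 and a mean count of at least 50. Where fewer than 5 genes passed in a direction, the 2 with the smallest p are given.

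Expected counts were rounded to whole numbers, which changed library totals by at most 0.00038%. Library names have 2 forms. The sequencer's sample numbers repeat between the forms but never within 1, so the forms were taken as 2 library sets. Sets 1 and 2 hold 3 and 3 libraries in each group from air-exposed dams, and 2 and 4 in each group from ozone-exposed dams. The library set was a covariate in each test across genes. Counts were tested with edgeR 4.0.16 in R 4.3.3, by its robust quasi-likelihood test with TMM normalization. Genes were kept by filterByExpr, with a minimum count of 10 and a minimum total of 15. A gene is called where its Benjamini-Hochberg adjusted p is under 0.05. Each sex was fitted by itself (12 libraries). All 24 libraries were fitted together for the difference between the sexes, overall and within each dam group, and for the interaction of sex with maternal exposure. Standard errors are those implied by the test statistic. CPM values were computed from the deposited counts after TMM normalization, and log2 CPM used a prior count of 2. Principal components were computed on log2 CPM of 12854 genes.

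The tests within each sex, the interaction and the averaged sex difference were fixed before the data were examined. Except where stated below, all other tests were chosen after the first fits and the principal components had been seen. These are the sex difference within each dam group, the sex-biased gene groups and their set tests, the sex score, the tests of principal component 1, and the tests of identical or fractional gene IDs. Sex-biased genes are those called in the averaged sex difference at 2-fold or more (log2 of at least 1). The sex score of a library is the mean log2 CPM of the male-biased genes minus that of the female-biased genes. Gene groups were tested with camera and fry of limma 3.58.1. Scores were compared with exact two-sided permutation tests over 924 arrangements, and the change of the gap between the sexes with 100000 resamples. The correlation across genes between the sexes was compared with 2000 permutations of the dam labels.

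Library totals ran from 8462290 to 14564700 counts, apart from 1 library at 36232100. The limit that 3 counts set lay between 0.0828 and 0.355 CPM, covering counting error only. The fits were tested on simulated data with genes changed by known folds. In males, 47 of 100 genes changed 1.5-fold and 85 of 100 changed 2-fold were recovered, with 9 false calls. The numbers were 38, 92 and 3 in females, and 19, 65 and 6 for the interaction. Simulated genes varied independently of each other and without a library set effect. These numbers may therefore not carry over to the real libraries, where genes vary together. Alternatives were DESeq2 1.42.0, limma-voom, RLE normalization, library totals only, no filter, a mean count of at least 50, no library set term, each set alone, all libraries in 1 fit, and each library left out in turn. Pairs of replicates differed by 17.2 to 91.8 per gene in chi-square over 60 pairs, so none was a copy of another. Figures were drawn with matplotlib 3.10.9.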

Results

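Livers were collected at about postnatal day 48 from rats whose dams had breathed either clean filtered air or ozone (0.8 ppm, 4 hours a day) on gestation days 5 and 6, with 12 dams per exposure. All offspring described here were themselves exposed to ozone once a week in postnatal weeks 5 to 7, at 0.4 ppm in week 5 and 0.8 ppm in weeks 6 and 7. The comparisons ask whether maternal ozone changed hepatic expression in ozone-exposed offspring, and whether it did so differently in males and females. Each of the 4 groups held 6 animals. Library totals were 9643330 to 14564700 estimated counts in males from air-exposed dams and 8462290 to 13173600 in males from ozone-exposed dams. They were 9210460 to 13779100 in females from air-exposed dams and 10126000 to 36232100 in females from ozone-exposed dams, where the second highest library had 12094600. The 10 most abundant genes held between 22.6% and 25.3% of the counts on average in each group. All 10 of the genes with the clearest sex difference (5 higher in each sex) separated the 24 libraries by labelled sex, but they were chosen on the same labels, so this is no independent check.

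In male livers, maternal ozone went with higher expression of 1295 genes and lower expression of 1375, together 2670 of 12541 tested genes (21.3%; edgeR, adjusted p under 0.05). The changes were mostly small. The median size among called genes was 0.58 on the log2 scale, and 51.0% of them changed by less than 1.5-fold. More than 2-fold changes were found in 111 risen and 172 fallen genes. The risen genes held 8.30% ± 0.53 of all counts in males from air-exposed dams and 12.0% ± 1.77 in males from ozone-exposed dams (SD, n = 6 each). The fallen genes held 10.3% ± 1.10 and 7.03% ± 0.81. These genes were chosen for that difference, so the shares describe its size and are not further evidence of it. At an unadjusted p under 0.05, 4393 genes differed, against 627 expected by chance.

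Among the largest rises in males, ENSRNOG00000055561 went from 9.35 ± 10.7 CPM to 113 ± 76.2 CPM (SD, n = 6 each; log2 fold change 3.96 ± 0.57 SE, edgeR adjusted p = 0.0022). ENSRNOG00000049893 had the largest fitted rise (5.49 ± 1.15 SE, adjusted p = 0.0099), but from 0.260 ± 0.57 CPM, near the limit of detection, to 9.32 ± 15.1 CPM, with single libraries up to 39.9 CPM. In 1 of the 6 males from ozone-exposed dams, replicate 2, it was below 3 counts. Its log2 fold change was 7.59 without air replicate 1, 6.19 without ozone replicate 4 and 4.07 without ozone replicate 5. ENSRNOG00000046349 fell from 8.89 ± 3.61 to 0.734 ± 1.37 CPM (log2 fold change -3.98 ± 0.76, adjusted p = 0.0058; -5.57 without ozone replicate 1, -6.92 in library set 1 alone and -5.36 with limma-voom). In 4 of the 6 males from ozone-exposed dams it was below 3 counts, and replicate 1 was at 3.47 CPM, so the size of the fall is uncertain. ENSRNOG00000030807 fell from 26.9 ± 9.99 to 5.06 ± 2.47 CPM (-2.49 ± 0.36, adjusted p = 0.0016). ENSRNOG00000049893 and ENSRNOG00000046349 had fractional counts in 12 of the 12 male libraries and ENSRNOG00000030807 in 11, so part of their reads was shared with other genes. The call of ENSRNOG00000049893 was lost with limma-voom and within either library set alone, those of ENSRNOG00000055561 and ENSRNOG00000030807 within set 1 alone, and that of ENSRNOG00000046349 within set 2 alone. With 1 animal of either dam group left out, the count ranged from 1684 (without air replicate 5; 1758 without air replicate 4) to 3740 (without ozone replicate 2). In library set 1 alone (3 against 2 animals) 861 genes were called, and in set 2 alone (3 against 4) 121.

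In female livers, 34 of 12538 genes passed the same test, and this count was fragile. Of the 34 genes, 30 rose and 4 fell with maternal ozone, and 20 of the rises were more than 2-fold. No gene was called without air replicate 6, although 2053 genes then had an unadjusted p under 0.05 in edgeR. The smallest adjusted p was then 0.0536, and the median log2 fold change of the 30 risen IDs was 1.75 (median SE 0.29) against 1.78 (0.25) with all animals. With the other libraries left out in turn, between 14 and 135 genes were called. DESeq2 called 336 genes. At an unadjusted p under 0.05, 2001 genes differed, against 627 expected.

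The risen genes in females held 0.530% ± 0.20 of all counts in offspring of air-exposed dams and 2.34% ± 0.66 in offspring of ozone-exposed dams (SD, n = 6 each). As in males, these genes were chosen for that difference, so the shares are not further evidence of it. IDs with identical counts enter these shares more than once. ENSRNOG00000047746 went from 1842 ± 758 to 10149.9 ± 3763 CPM (log2 fold change 2.51 ± 0.33 SE, edgeR adjusted p = 0.0102). ENSRNOG00000060518 went from 1256 ± 551 to 5919 ± 1523 CPM (2.30 ± 0.30, adjusted p = 0.0102), with fractional counts in 11 of 12 libraries. In males from air-exposed dams, ENSRNOG00000047746 ranged from 1401 to 29104 CPM. ENSRNOG00000048152 fell from 71.6 ± 7.97 to 43.3 ± 6.48 CPM (-0.73 ± 0.12, adjusted p = 0.0171), and ENSRNOG00000037768 from 11.2 ± 1.31 to 7.29 ± 0.47 CPM (-0.64 ± 0.11, adjusted p = 0.0214). All 4 of these calls were lost without air replicate 6, within either library set alone, and in the fit of all 24 libraries. That of ENSRNOG00000048152 was also lost without air replicate 5, and that of ENSRNOG00000037768 without air replicates 3, 4 or 5 and ozone replicates 3 or 4. Of the 30 risen IDs, 23 had fractional counts and 12 had counts identical to those of another ID, so the 34 called IDs were 25 distinct measurements. With identical IDs kept once, 15 were called.

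**Figure D1:**
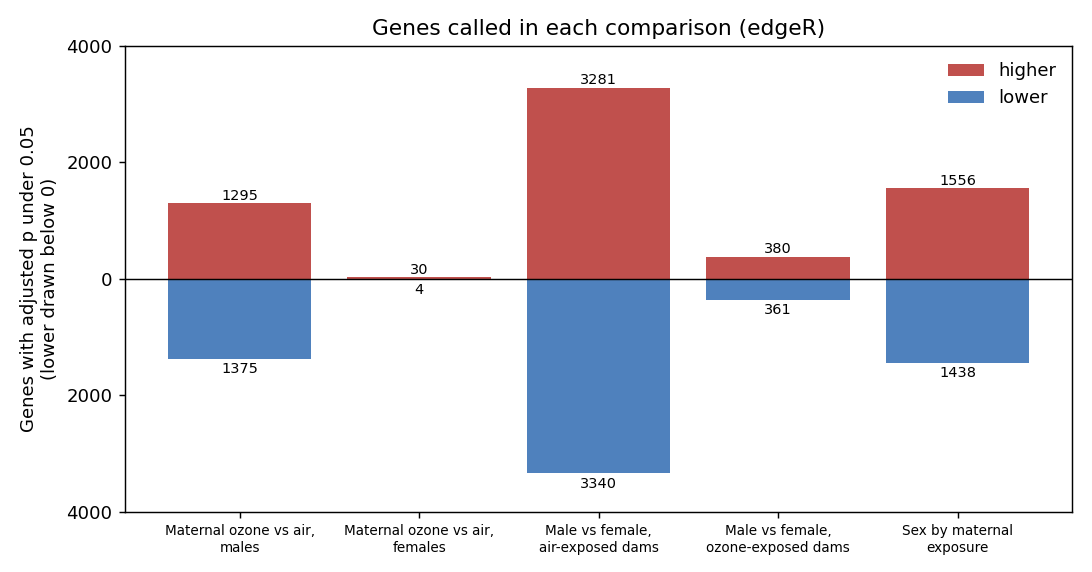
Number of genes with adjusted p under 0.05 (edgeR) in 5 comparisons, with genes higher drawn above 0 and genes lower drawn below it; for the last bar the sign is that of the male minus the female maternal difference. Maternal ozone against air gave 1295 higher and 1375 lower genes in males and 30 and 4 in females.

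The maternal difference itself differed between the sexes in 2994 of 12854 genes (edgeR test of the interaction, 24 libraries; 1556 with a more positive difference in males and 1438 with a more negative one). Of these genes, 98.1% had fitted maternal differences of opposite sign in males and females, and the male difference was the larger in 80.1%. Choosing genes by the interaction favours opposite signs, so the first percentage largely follows from that choice. Over 12701 genes tested in both library sets, of 432 genes called in set 1 alone, 99.3% had the same sign in set 2, and of 448 called in set 2, 98.2% had the same sign in set 1. The 2 sets call far fewer genes than all libraries together, with 131 called in both, all in the same direction.

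Across 12250 genes tested in both sexes, the male and female log2 fold changes had a Pearson r of -0.37 and a Spearman rho of -0.49. Genes are not independent replicates, and the 2 fits share no libraries. When dam labels were permuted within each sex, r for the corresponding differences in mean log2 CPM over 9341 genes was -0.39, with a permutation p of 0.0610. That correlation therefore did not exceed what relabelled animals gave, whose central 95% ran from -0.41 to 0.41. Among 9 genes called in both sexes, 8 changed in opposite directions and 1 in the same direction. Of the 8, 6 fell in males and rose in females (3.20 expected from independent calls), and 2 did the reverse (0.42 expected). The other gene rose in both (3.06 expected), and 0 fell in both (0.44 expected). Some IDs called in females had identical counts, so the 9 may not be separate measurements.

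**Figure D2:**
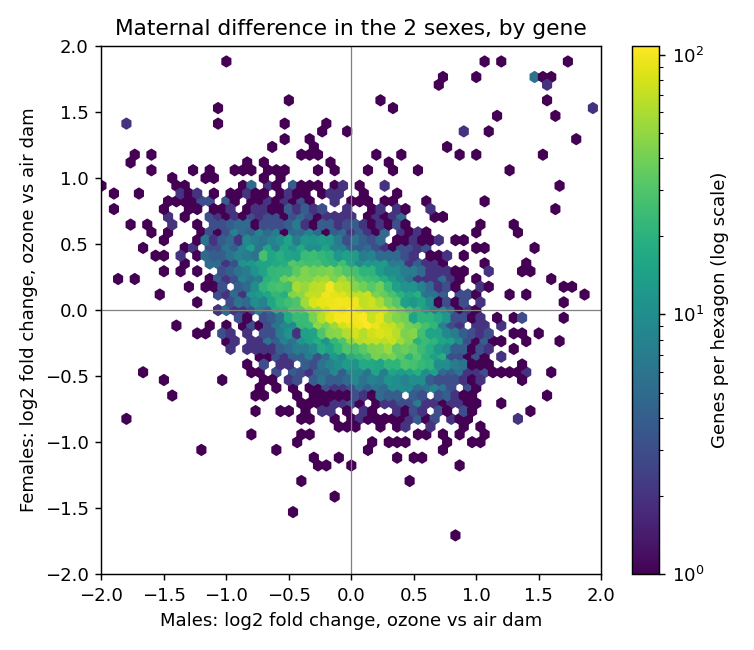
Log2 fold change of maternal ozone against air in males (horizontal) and females (vertical) for 12195 genes, with 55 genes outside the axes left out; colour gives the number of genes per hexagon on a log scale. The cloud of genes slopes from upper left to lower right, with Pearson r of -0.37 over all 12250 genes.

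Male and female livers differed in 5867 of 12854 genes when averaged over dam groups (2893 higher and 2974 lower in males; edgeR, 24 libraries). Among offspring of air-exposed dams 6621 genes differed between the sexes, and among offspring of ozone-exposed dams 741 did. Of the 6621 genes, 558 were also called with ozone-exposed dams in the same direction and 13 in the opposite one. Of the genes called only with air-exposed dams, 2765 also passed the test of the interaction. Most of them did not pass it, so a change of their sex difference was not shown. The genes called with air-exposed dams, of which 72.8% had the same sign with ozone-exposed dams, differed less there. Their median absolute sex difference was 0.71 on the log2 scale with air-exposed dams and 0.17 with ozone-exposed dams. Part of that decrease comes from choosing genes on the first value. Over the 9341 more abundant genes, chosen on neither, the SD of the sex difference after removal of the estimation error was 0.80 and 0.53.

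Among genes at least 2-fold higher in 1 sex, most calls in males were toward the level of females. Of 267 male-biased genes, 47 fell and 4 rose in males, with a median log2 fold change of -0.20. Of 207 female-biased genes, 70 rose and 2 fell, with a median of 0.42. Calls were made in 19.1% of the male-biased and 34.8% of the female-biased genes, against 21.1% of genes biased to neither sex. Male-biased genes were thus not called more often than those, and only their direction stood out. In females none of 175 male-biased and 282 female-biased genes was called by edgeR, and the medians were 0.25 and -0.17. Adjusted camera p-values with a preset correlation were 0.0030 and 2.61e-09 in males, and 2.49e-05 and 0.0013 in females. None held with an estimated correlation (adjusted p = 0.432, 0.220, 0.220 and 0.309 with an estimated correlation, in the same order). With fry, the female-biased genes in males alone passed (adjusted p = 0.0227, the others 0.134, 0.0590 and 0.163). The groups were defined on these same libraries. Defined on 3 animals per group and measured in the others, the medians in males were -0.48 and 0.46 in 1 direction and -0.10 and 0.33 in the other. In females they were 0.42 and -0.42, and 0.20 and -0.05.

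The sex score was 2.40 ± 0.38 in males from air-exposed dams and 1.67 ± 0.66 in males from ozone-exposed dams (SD, n = 6 each; exact permutation p = 0.0433, 0.0577 after adjustment over 4 tests). In females it was -1.86 ± 0.22 and -1.53 ± 0.37 (exact permutation p = 0.0952, adjusted 0.0952). Principal component 1, with 40.0% of the variance, separated the sexes. Its score was 47.0 ± 5.98 and 21.1 ± 18.1 in males (exact permutation p = 0.0130, adjusted 0.0519), and -41.9 ± 9.66 and -26.2 ± 10.2 in females (exact permutation p = 0.0303, adjusted 0.0577). None of these 4 differences passed the adjustment. The gap in sex score between males and females was 4.26 with air-exposed dams and 3.19 with ozone-exposed dams, a change of -1.07 (permutation p = 0.00754). That p-value was not part of the adjustment, and its permutations took no account of library set. Within library set 1 the maternal difference in sex score was -1.36 in males and 0.05 in females (3 against 2 animals, where an exact p cannot go below 0.1). Within set 2 it was -0.41 and 0.55 (3 against 4; exact permutation p = 0.314 and 0.114).

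**Figure D3:**
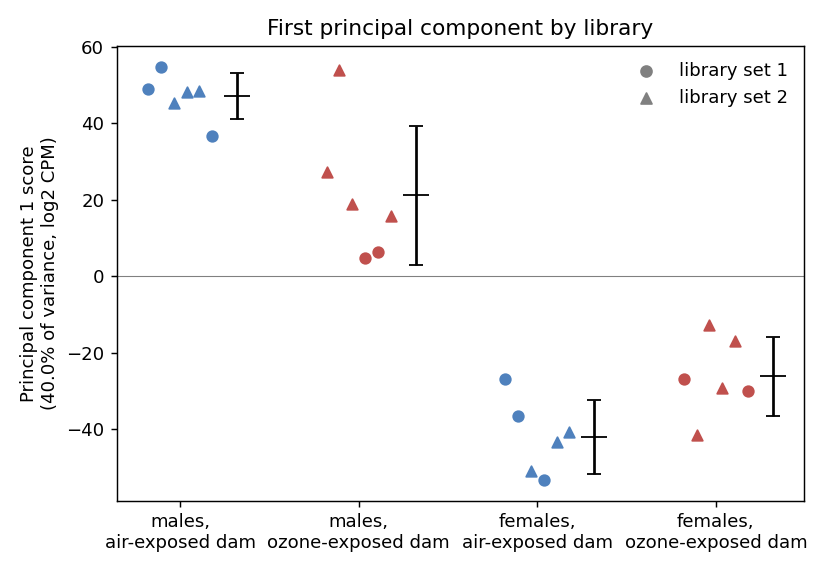
Principal component 1 score (arbitrary units, from log2 CPM) of each of the 24 libraries by group, with circles for library set 1 and triangles for library set 2; bars give the mean and SD of 6 libraries. The score of 1 male from an ozone-exposed dam, 54.0, lies among those of males from air-exposed dams (36.6 to 54.8), and the other 5 lie between 4.66 and 27.1.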

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

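The tests of mixed RNA, library set, shared spread, shared reads and the size of the female rises were chosen only after the results were seen; the test of mixed RNA in males was run in 5 versions and in females in 2, each after the one before was seen, and the share that the last version in males uses was already known.

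The maternal difference differed between the sexes in 2994 genes, and the gap in sex score changed by -1.07 with maternal ozone. The test of that gap was not adjusted with the other score tests. Of 60 relabellings, the real one included, only the real one gave as many genes, and the highest other gave 61. That number of draws cannot show a share below 1 in 60. Single animals were relabelled, so grouping by litter was not covered. The values argue against library set and depth as the whole cause: at least 98.2% of genes called in 1 set had the same sign in the other (a first version on genes chosen in all libraries, 99.9%, was void), and 2816 genes were called without the deepest library. The share read from 58 female-higher genes also argues against female RNA in the libraries of males as the whole cause. It was 1.98% ± 3.89 (SD, 6 libraries), and even a share of 9.77% (mean plus 2 SD) lowers no gene by more than 0.15 log2. Of the 1375 genes called lower in males, 957 (69.6%) fell beyond that (edgeR threshold test, adjusted p under 0.05). This holds only if those 58 genes did not also fall for another reason. They were chosen on a sex difference averaged over both dam groups, so the same males helped to choose them. Genes that mixing raised in those males were less likely to be chosen, which can lower the share. The 1375 genes had already been called for a fall, which favours a high percentage. The 4 earlier versions decided nothing. Of the 58 genes, 29.3%, 51.7% and 32.8% lay below the rise that mixing needs, from shares that are no valid bound. Shares from male-higher and female-higher genes differed by -4.97 percentage points on average (exact sign-flip permutation p = 0.750). Male-higher genes gave widely varying shares, of 35.4%, 29.8% and 22.2% in male ozone replicates 3, 4 and 5. In male ozone replicates 1, 2 and 6 they gave -1.97%, -65.8% and -37.6%. Shares as high as those in replicates 3, 4 and 5 would allow falls beyond 0.15 log2, so that bound rests on the female-higher genes. Male RNA in the libraries of females cannot change those of males, where 2670 genes were called in a fit without females. The male maternal difference was the larger in 80.1% of the 2994 genes. Both values argue against such RNA as the whole cause. In females from ozone-exposed dams, the share read from 92 male-higher genes was 0.236% ± 0.351 (SD, 6 libraries), and 0.810% at most. Even at 0.938% (mean plus 2 SD), mixing lowers no gene by more than 0.0136 log2. That argues against such RNA as more than a small part of the cause. It holds only if those 92 genes did not also fall for another reason, and the same females helped to choose them. A small part stays open, as only 4 genes were called lower in females (100% of them beyond that fall), too few to decide. In a void version, 41.3% of 92 male-higher genes lay below the rise. Litter, the order of collection and a biological effect of maternal exposure also stay open, untested. Rat numbers and library index numbers in the labels run in ranges that do not overlap between groups. An effect of either order can therefore not be told apart from that of the group.

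More genes were called in males (2670) than in females (34), a gap that was smaller with DESeq2 (3059 and 336) and in the SD of fold changes after removal of the estimation error (0.37 and 0.20 log2). A single male library does not account for it, as at least 1684 genes were called with any 1 left out. A different spread between animals does not either: with a shared spread, 2598 genes were called in males and 1 in females. Relabelling the males gave 1 of 100 splits as large, the real one, but the highest other called 2128. That split exchanges air replicate 6 and ozone replicate 2 and keeps the dam labels of the other 10 males.

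The rises in females lay mostly in IDs that share reads: 76.7% of the risen IDs had fractional counts, against 22.1% of tested IDs; over distinct measurements 15 of 25 called were fractional (against 21.9% of those tested, Fisher's exact test p = 4.24e-05), and among male and interaction calls 27.4% and 25.9% were (against 22.0% in each). Several risen IDs may therefore count the same reads. By a test written before the result, the calls depended on several single libraries: of the 30 risen IDs, 0 were called without air replicate 6 (edgeR, 2053 genes at an unadjusted p under 0.05), 12 without air replicate 5 and 13 without ozone replicate 1. The median log2 fold change of the risen IDs stayed at or above 1.64 with any library left out, against 1.78. These IDs had been called in the same libraries, with a median SE of 0.25, which favours that outcome. Identical IDs also enter that median more than once. It therefore does not decide whether a single library made the size of the rises. Relabelling the females gave 2 of 100 splits with as many genes, the real one included. The highest other called 239, several times the real 34. It exchanged air replicate 1 and ozone replicate 2 and kept the other 10 labels, and the cause of its count was not tested.

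The averaged sex difference gave 1 of 60 relabellings as large, the real one with 5867 genes, and 3684 in the highest other. That relabelling exchanged sexes only among offspring of ozone-exposed dams, so it kept the sex difference among offspring of air-exposed dams. In 3 of 48 groups of 6 values tested, 1 value lay far from the rest, where chance flags about 1 in 20. Female ozone replicate 6 had 36232100 counts, against 12094600 in the next. ENSRNOG00000049893 was at 0.94 on the log2(CPM + 0.5) scale in male air replicate 1, with the next at -0.82. ENSRNOG00000046349 was at 0.38 on that scale in female air replicate 1, with the next at -0.91. The male minus female maternal difference passed the edgeR interaction test at 5.26 log2 for ENSRNOG00000049893, 3.45 for ENSRNOG00000055561, -7.52 for ENSRNOG00000046349 and -3.80 for ENSRNOG00000030807. It was 1.26 for ENSRNOG00000048152 and 1.11 for ENSRNOG00000037768. The IDs with the largest rises in females did not pass that test. Their values were -2.12 for ENSRNOG00000047746 (edgeR interaction adjusted p = 0.0965) and -2.07 for ENSRNOG00000060518 (0.0802), so these rises were not shown to be particular to females. The values for ENSRNOG00000049893 and ENSRNOG00000046349 depend on groups near 0: for ENSRNOG00000049893, 5 of 6 males from air-exposed dams were below 3 counts, and for ENSRNOG00000046349, 5 of 6 females from air-exposed dams and 4 of 6 males from ozone-exposed dams.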

How the results depend on the processing

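Keeping identical IDs once, and the alternatives for the sex difference within dam groups and the left-out libraries of the interaction, were chosen after seeing the data. Gene list alternatives were not run, as no list could be tested, and those for normalized values do not apply to counts. No reported fold change of an ID changed sign. The balance of higher and lower calls turned in males with DESeq2 (1532, 1527), no library set term (1074, 1065), all 24 libraries in 1 fit (1310, 1288), set 2 alone and without ozone replicate 5 (907, 884). It turned for the interaction with limma-voom (1468, 1500), either set alone and without male ozone replicate 4 (1185, 1191). In males 2139 to 3059 genes were called under the settings not named next, and 2634 to 3283 for the interaction. Set 1 alone called 861 genes in males (417 higher, 444 lower) and set 2 alone 121 (73, 48), with fewer samples. Leaving out 1 library gave 1684 to 3740 (752 to 1829 higher, 884 to 1911 lower). The lowest were air replicates 5 (1684; 752 higher) and 4 (1758; 833 higher) and, for lower genes, ozone replicate 5 (884). For the interaction, set 1 alone called 432 (195, 237) and set 2 alone 450 (148, 302), and left-out libraries gave 2371 to 3793. In females DESeq2 called 336 genes (211 higher, 125 lower; adjusted p NA for 1 of the 34), no library set term 66 (53, 13), and no filter 7 lower. Set 1 alone called 9 (9, 0), set 2 alone 0 (0, 0; 1453 at an unadjusted p under 0.05), all 24 libraries in 1 fit 1 (1, 0), and identical IDs kept once 15 (12 higher). The cause of the differences between tools was not tested. Leaving out 1 female library gave 0 to 135 genes (0 to 91 higher, 0 to 44 lower). Without air replicates 1, 2, 4, 5 and 6 the counts were 135, 20, 19, 14 and 0, and without ozone replicates 1, 3, 4 and 6 they were 19, 20, 19 and 64. The sex difference gave 6102 to 6851 genes with air-exposed dams and 554 to 945 with ozone-exposed dams. For the 8 IDs, 156 refits kept the call and 28 lost it. Depth limits low genes: 3 counts are 0.0828 to 0.355 CPM.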

Other observations

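The sex score was chosen after the data had been seen, and leaving out each library before. Among males from ozone-exposed dams the sex score ran from 1.02 in replicate 4 to 2.82 in replicate 2, and in males from air-exposed dams from 1.82 to 2.78. The score of 2.82 lay above all 6 animals from air-exposed dams. Without that animal 3740 genes were called in males, against 2670 with it. The labels give nothing that sets this animal apart.

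The library set itself called 0 genes in either sex by edgeR. At an unadjusted p under 0.05 it gave 1128 genes in males and 237 in females, against 627 expected in each.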
